A study of Mus musculus with 2 samples.

How the data were processed

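The series measured messenger RNA by sequencing in cultured mouse primary hepatocytes, in 1 library from cells given control lentivirus and 1 library from cells given lentivirus carrying an shRNA against JMJD3. Per the labels, each group was a pool of cells from 5 C57BL/6 mice, infected 24 h after plating and kept for 48 h with the virus. Both cultures then received 5 mM glucose and 10 µM forskolin, an activator of adenylyl cyclase, for 6 h to imitate fasting. Libraries were read as 100 bp paired ends, per the labels. No library of uninfected cells or of cells without forskolin was used here. The groups were taken from the sample titles.

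Per the submitters' processing notes, the tools named were bcl2fastq 2.17.1.14, Trimmomatic 0.36, FastQC 0.11.5, STAR 2.5.3a and edgeR, with the mm9 genome build. The role and order of these tools and the version of edgeR are not given in the sources used here. The deposited counts are whole-number read counts per gene, made with featureCounts 1.4.6-p4 from coordinate-sorted STAR alignments, per the file headers. Exons were grouped by gene in UCSC gene models for mm9, and strand was not used, per the file headers. The recorded command held no option for counting read pairs, so the deposited counts take each aligned read of a pair on its own. No option for reads that map to several places was recorded, and the default of that program leaves such reads, and reads that overlap several genes, uncounted. Genes with near-identical copies, such as major urinary proteins, glutathione transferases and cytochromes P450, and genes that overlap another on either strand therefore have uncertain counts. The deposited length of each gene is the summed length of its exons in bp, per the file headers. Gene models of the mitochondrial chromosome were not among those counted, so the 15 mitochondrially encoded genes sought have no value.

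The authors' deposited table of the comparison gives a log2 fold change and an average log2 CPM, that is counts scaled to library size, for each of 12838 genes. The p-values and adjusted p-values in the authors' deposited table carry no statement of the test or of the spread they assume. Its fold change had the same sign as the knockdown over control ratio of the counts in 12607 of 12607 genes compared, which sets its direction. All 12838 genes were in the count files, and the larger of a gene's CPM values in the libraries was at least 1.036 in the table and at most 0.991 outside it. When edgeR's exact test was rerun on the counts with an assumed biological coefficient of variation of 0.1, it called 3396 genes at an adjusted p-value threshold of 0.05, against 3392 in the authors' deposited table, with 3361 in both. The median absolute difference between these p-values and those of the authors' deposited table was 0.00323 and the largest was 0.114. An assumed spread near that value is thus inferred from the match and is not stated in a label or header.

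Counts were scaled by library total and TMM factors from edgeR 4.0.16 in R 4.3.3. A gene was taken as measured when the mean of its TMM-scaled CPM over both libraries was at least 1. The log2 ratio of knockdown over control was computed without a pseudocount, with an exact conditional binomial (Clopper-Pearson) 95% interval from the counts. A count of 0 was set to a floor of 3 counts and its ratio was given as a bound. With 1 library per group there is no spread between replicates, so no p-value is reported for any gene or list beyond those of the authors' deposited table. The rerun of edgeR's exact test above served only to compare its p-values and calls with that table. A rule of size stands in its place: a gene passed as higher or lower when the ratio was at least 1.5-fold from 1 and its interval excluded 1. These intervals and floors cover counting error only. They are too narrow where both reads of a pair, or copies made by PCR, were counted.

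Gene lists, the rule of size and the rule for named genes were fixed before the data were examined. The named genes are Kdm6b, members of the mitochondrial beta-oxidation and ketogenesis lists, and the 12 genes highest and 12 lowest in the knockdown library among those with a mean of at least 5 CPM. These were ranked by the interval bound nearest to 1, and genes without a proper symbol were left out. In every other list the 2 most abundant members, the highest and the lowest were named, and any gene named beyond this was chosen after its values were seen. Some genes that this rule takes are not reported here. For each list the median log2 ratio of its measured members was set against 10000 random lists of the same size drawn within 20 bins of mean expression. The median's own range is the central 95% over 500 redrawn sets of counts. Members of a list are often regulated together, so its place among random lists describes these 2 libraries and is not a test of the conditions. Several lists share members.

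The procedure was tested on simulated data with the real means and library sizes, with 200 of 12575 genes changed in this comparison. With counting noise alone the intervals held the true ratio in 95.52% of genes. The rule recovered 66 of 66 genes changed 4-fold, 62 of 67 changed 2-fold and 24 of 67 changed 1.5-fold, and it passed 78 of 12375 unchanged genes. With an added biological coefficient of variation of 0.1 the intervals held the true ratio in 60.3% of genes and the rule passed 240 unchanged genes, and with 0.2 these were 41.34% and 2042. Of 200 simulated unchanged lists, 9 lay outside the central 95% of their random lists. Their members were drawn at random with added independent normal noise, so this does not cover lists whose members are regulated together.

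Alternatives covered the scaling (DESeq2 1.42.0 size factors, totals alone, upper quartiles), the expression minimum (none, or 5 CPM), a prior count of 2, a 2-fold threshold, a 99% interval, and the mean in place of the median. They also covered removal of a lowess trend on expression or on exon length, and random lists matched on length as well or not matched. Added after the data were seen were removal of a trend on GC content and halved counts to stand for read pairs. Also added then was omission of 604 measured genes whose exons overlap another gene over at least 10% of their length. Other assumed spreads for the rerun of edgeR's exact test were likewise added after the data were seen. GC content came from GENCODE M21 transcripts on GRCm38, and coordinates are those of the files, in mm9. Older gene symbols were matched through tables of current names. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The control library held 11099562 counts and the knockdown library 18334366, so that 3 counts correspond to 0.267 and 0.166 CPM.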

Results

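RNA was sequenced from cells that the labels call primary mouse hepatocytes, liver cells isolated from the animal and kept in culture, after infection with control lentivirus or with lentivirus expressing an shRNA against the histone H3 lysine 27 demethylase JMJD3, encoded by Kdm6b. Each group was 1 library from a pool of 5 mice, and all cells had been treated with forskolin and low glucose to imitate fasting. The title of the series names fasting-induced JMJD3 and mitochondrial fatty acid beta-oxidation, so the comparison asks how transcripts of this pathway and of other liver programmes differ when JMJD3 is reduced. The control library held 11099562 counts over 15856 genes and the knockdown library 18334366 over 16282 genes, a 1.65-fold difference in depth. Clu took the most counts in both, 2.59% in control and 2.28% in knockdown, and the top 10 genes held 7.01% and 6.54%. None of the differences below has a replicate check, and the intervals given are exact binomial 95% intervals of the counts.

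Kdm6b was lower in the knockdown library, at 33.0 CPM against 90.7 CPM in control, from 598 and 1019 counts. The ratio was 0.364 with an interval of 0.329 to 0.403. The gene lies on the minus strand of chromosome 11 from 69212020 to 69227177 in mm9, with 23 exons in the files. The authors' deposited table gives Kdm6b a log2 fold change of -1.46 with an adjusted p-value of 1.13e-09, for which no source used here states the test or the spread between samples. Among 13 measured members of the H3K27 methylation machinery, which includes Kdm6b, only Kdm6b passed the rule of size as lower. Only Aebp2, a cofactor of Polycomb repressive complex 2, passed as higher, at log2 0.76. The most abundant members, the histone-binding proteins Rbbp4 and Rbbp7, had log2 ratios of -0.13 and 0.26, and the median of the list, 0.13, lay inside the range of random lists of -0.25 to 0.37.

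Transcripts for mitochondrial fatty acid beta-oxidation were lower in the knockdown library. All 21 measured genes of the list had ratios below 1, and 6 passed the rule of size. Cpt1a, the carnitine palmitoyltransferase that controls entry of long-chain fatty acids into mitochondria, had 241 CPM against 959 CPM in control, a log2 ratio of -1.99 (-2.04 to -1.94). Cpt2, its partner on the inner membrane, stood at -1.66 (-1.81 to -1.50), and the acyl-CoA synthetase Acsl1 at -1.11 (-1.24 to -0.99). The medium-chain acyl-CoA dehydrogenase Acadm was at -0.97, the thiolase Acaa2 at -0.78 and the isomerase Eci1 at -0.70. The other 15 genes lay closer to 1, among them the trifunctional protein subunit Hadha at -0.22 and the electron transfer enzyme Etfdh at -0.15. The median log2 ratio of the list was -0.44, with a range of -0.48 to -0.37 over redrawn counts. Its members spread with a standard deviation of 0.48. Of 10000 random lists of matched expression, 0 had a lower median, and their central 95% ran from -0.19 to 0.30.

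Ketone body synthesis genes followed with 2 of 5 passing as lower. The dehydrogenase Bdh1 was at -0.71 (-1.08 to -0.34), on 128 and 126 counts, and the intervals of Acat1 at -0.07 and Slc16a6 at -0.08 included no difference. With 5 genes the median of -0.54 fell just inside the range of random lists, and 256 of 10000 were lower. It lay below that range under 2 alternatives, at percentiles of 1.67 with random lists matched on length and 2.09 with overlapping genes left out, the latter chosen after the data were seen. Slc16a6 shares exonic sequence with another gene over part of its length, so its count is uncertain.

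**Figure D1:**
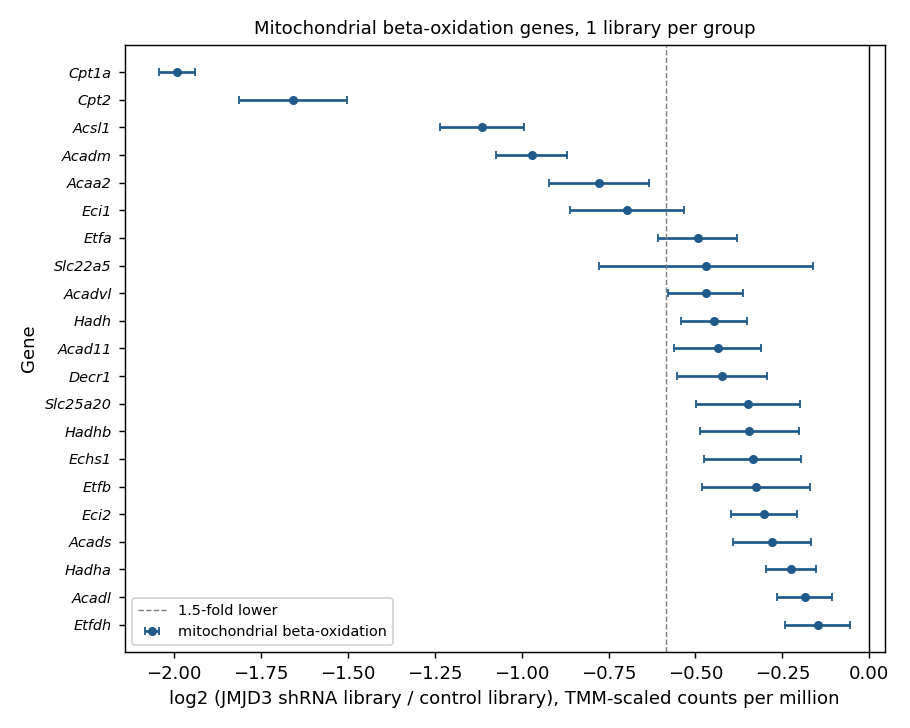
Log2 ratio of TMM-scaled CPM, knockdown library over control library, on the horizontal axis for each of the 21 mitochondrial beta-oxidation genes on the vertical axis. Points are the ratios of 1 library per group, bars are exact binomial 95% intervals of the counts, and the dashed line marks 1.5-fold lower; Cpt1a at -1.99 lies farthest to the left.

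In the authors' deposited table, 6 of the 21 beta-oxidation genes had an adjusted p-value under 0.05 and a negative fold. In the authors' deposited table Cpt1a had a log2 fold change of -1.99 with an adjusted p-value of 6.32e-19, and Hadha one of -0.22 with 0.471. When edgeR's exact test was rerun with assumed coefficients of variation of 0.2 and 0.4, 2 and 0 of the 21 genes were called lower. The list median was -0.33 once a trend of the ratio with exon length, present across all genes, had been removed.

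Peroxisomal beta-oxidation and the targets of PPARalpha, the nuclear receptor that drives fatty acid use in fasting, were also lower. In the peroxisomal list 6 of 14 genes passed as lower and 0 as higher, with all 14 ratios below 1 and a median of -0.47. The sterol carrier thiolase Scp2 was lowest at -2.49, the carnitine octanoyltransferase Crot was at -1.29, while Acot8 at -0.15 had an interval that included 1. Among PPARalpha targets, which also hold Cpt1a, 10 of 18 passed as lower and 3 as higher, with a median of -0.74. Plin2, which coats lipid droplets, was the highest at 718 CPM against 372 CPM (log2 0.95). The fasting hormone Fgf21 was the lowest at -2.20, on 20 counts in control and 7 in knockdown. Of 10000 random lists, 8 were lower than the peroxisomal median and 0 lower than the PPARalpha median. Of 22 PPARalpha targets sought, Cyp4a10, Cyp4a14 and Cyp4a31 had 0 counts in both libraries and Fabp1 had 2 in each. These targets were not measured. The transcript of the receptor itself, Ppara, was at -0.24 with an interval that included 1.

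Genes of the gluconeogenesis list and of the cyclic AMP response were more often lower than higher. In gluconeogenesis 7 of 14 genes passed as lower and 0 as higher, with a median of -0.65. Tat, the tyrosine aminotransferase induced by cyclic AMP and glucocorticoid, was at 82.9 CPM against 1514 CPM (log2 -4.19, interval -4.27 to -4.11). Gpt2 was at -0.72 and Pck2, the mitochondrial form of the carboxykinase, at 0.40. Pck1, its cytosolic form, chosen after its values were seen, was at -0.34 and did not pass. Nor did G6pc at -0.32, Pcx at -0.32 and Slc37a4 at -0.58. Among the 7 lower genes, Tat, Got1, Sds, Gpt2 and Tdo2 are enzymes of amino acid breakdown. In the cyclic AMP and CREB list 12 of 18 passed as lower and 4 as higher, with a median of -1.22. The orphan receptor Nr4a3 was lowest at -6.12 (-8.42 to -4.55) on 130 and 3 counts, G6pc, glucose-6-phosphatase, was at -0.32, and Fosb was highest at 2.38. The genes higher were Fosb and, named after their values were seen, Fos, Junb and Per1. For both lists 0 of 10000 random lists had a lower median.

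The transcription regulators of fasting held 17 measured genes, Kdm6b among them, with 6 lower, 2 higher and a median of -0.31. Cebpb was at -0.71, Hnf4a at -0.57 and Foxo3, highest of the list, at 1.31. Autophagy and lysosome genes had 7 of 26 lower and 0 higher, with a median of -0.30. Tfeb, a master regulator of lysosome genes, was lowest at -1.25, and the abundant Lamp1 and Ctsd were at -0.22 and -0.25. Of 10000 random lists, 60 were lower than the regulators and 12 lower than the autophagy list. The regulators came inside the random range when their mean replaced their median, at a percentile of 2.62.

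Most other nuclear genes of mitochondria lay below 1 without passing the rule of size. All 30 nuclear-encoded genes of oxidative phosphorylation had ratios below 1 and 6 passed as lower, with a median of -0.48 and a standard deviation of 0.15. Ndufa2 was lowest at -0.84, and the ATP synthase subunits Atp5a1 and Atp5b were at -0.43 and -0.39. In the tricarboxylic acid cycle 2 of 16 passed as lower and 0 as higher, with a median of -0.34. These were Fh1, fumarase, at 59.3 CPM against 374 CPM (log2 -2.66), and Mdh2, malate dehydrogenase, at -1.33, while Sdha was at -0.34 and Cs, citrate synthase, at 0.12. Outside mitochondria, cytosolic ribosomal protein genes, with 1 of 27 lower, had a median of -0.33, Rpl4 being highest at -0.16 and Rps19 lowest at -0.61. Random lists were lower than these medians in 0, 16 and 14 of 10000 draws. With the exon-length trend removed the medians were -0.17, -0.20 and -0.02, and the tricarboxylic acid cycle and ribosomal lists then lay inside the random range at percentiles of 3.06 and 41.14. With random lists matched on length those lists lay inside it too, at 2.79 and 28.01. Against lists drawn from 74 other nuclear genes of mitochondria, a comparison chosen after the data were seen, the beta-oxidation median lay at a percentile of 11.81, and at 0.11 once the length trend had been removed.

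**Figure D2:**
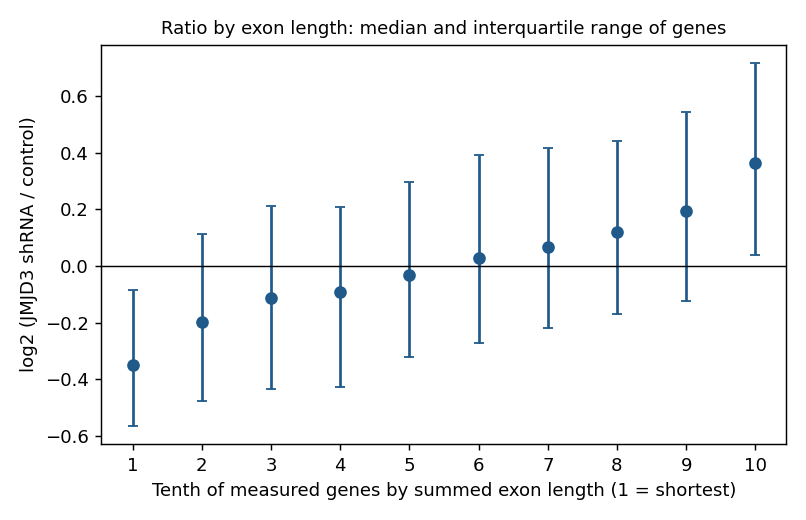
Median log2 ratio of knockdown over control on the vertical axis for 10 classes of the measured genes ordered by summed exon length on the horizontal axis, from shortest to longest. Points are medians and bars are interquartile ranges over genes, and the medians run from -0.35 in the class of the shortest genes to 0.36 in that of the longest.

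Genes of the differentiated hepatocyte were lower in the knockdown library. Some transcripts usually abundant in hepatocytes were near 0 in both libraries, with 2 counts of Fabp1 and 0 of Cyp2e1 in each. Among secreted proteins and identity genes 15 of 20 passed as lower and 1 as higher, with a median of -0.98. Cps1, the entry enzyme of the urea cycle, was at 3.87 CPM against 223 CPM (log2 -5.85), and fibrinogen Fgb at 846 CPM against 3987 CPM (log2 -2.24). Trf, transferrin, at -0.01 did not differ beyond its interval of -0.03 to 0.01, and Apob was higher at 0.78. Acute phase genes had 11 of 18 lower and 1 higher, with a median of -0.79. In that list Hpx was at -0.89, Cp at 0.42 and Serpina3n, the highest, at 0.61. Bile acid synthesis and transport had 8 of 10 lower and 0 higher, with a median of -1.24. In it the bile acid receptor Nr1h4 was at -0.94, Hsd3b7 at -0.43 and Cyp27a1 at -0.02. Cyp8b1 had 72 counts in control and 1 in knockdown, a log2 ratio of -6.86 (-12.18 to -4.33). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, chosen after its values were seen, had 37 counts in control and 0 in knockdown and was at least 19.9-fold lower against the floor of 3 counts. With the counting error of both counts included, the 95% bound was a log2 ratio of -3.94. For these 3 lists 0 of 10000 random lists had a lower median.

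Zonal and sex-biased liver genes had ratios mostly below 1 too, though most male-biased genes did not pass the rule of size. Periportal markers had 9 of 13 lower and 1 higher, with a median of -1.39. The lowest was Agxt2l1 at -6.40, and the adhesion gene Cdh1 was higher, at 318 CPM against 159 CPM. Pericentral markers had 7 of 12 lower and 1 higher, with a median of -0.88. The glutamine synthetase Glul was at 0.03, Aldh1a1 at -0.91 and Lgr5 at -4.73 (-7.84 to -2.77) on 33 and 2 counts. In drug metabolism 5 of 9 genes were lower and 3 higher, with a median of -0.85. The P450 reductase Por was at -1.81, the receptor Nr1i2 at -0.94, Cyp3a11 at -5.03 and Cyp2c50 at 1.68. Only 4 female-biased genes were measured, with a median of -4.82, Cyp17a1 at -7.72 (-10.01 to -6.17) on 394 and 3 counts being the lowest and Fmo2 at -0.04 the highest. Male-biased genes had 6 of 15 lower and 0 higher, with a median of -0.43. Mup21 was lowest at -3.38, Mup3 was at -0.82, Mup20 at -0.43 and Kdm5d at 0.34. Random lists were lower in 0 of 10000 draws for the periportal, pericentral and female-biased lists, in 47 for drug metabolism and in 107 for male-biased genes. With a minimum of 5 CPM the pericentral, drug metabolism and male-biased lists lay inside the random range, at percentiles of 31.77, 43.76 and 14.13. The male-biased list also lay inside it with no filter, at 3.46, and with random lists matched on length, at 3.49.

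Markers of macrophages, stellate cells and endothelial cells lay inside the range of random lists. Macrophage markers had 0 of 7 lower or higher, with a median of 0.28, and Lyz2 was at 0.28, Csf1r at 0.07, Folr2 at 0.71 and Ctss at -0.42. Stellate cell and fibroblast markers had 3 of 12 lower and 0 higher, with a median of -0.14. Col1a1 was at 0.03, Acta2 at 0.41, Des at 0.79 and Reln at -3.74. Sinusoidal endothelial markers had 3 of 12 lower and 1 higher, with a median of 0.09 and a mean of -0.02, which differ in sign. Eng was at 0.04, Cdh5 at -0.20, Oit3 at 1.13 and Stab2 at -1.03. Cholangiocyte markers were higher, 5 of 8 with 0 lower and a median of 0.59. Of these Krt7 was at 1.64, Sox9 at 0.59, and Spp1 and Epcam at 0.04 and 0.01. For the cholangiocyte list 104 of 10000 random lists were higher, and its median lay above their central 95%. Among blood and lymphoid markers only Itgam was measured, at 0.27 (-0.56 to 1.15).

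Inflammatory, immediate early and growth genes were higher in the knockdown library. NF-kappaB targets and cytokines had 12 of 17 higher and 2 lower, with a median of 1.12. The chemokine Ccl2 was at 489 CPM against 76.2 CPM (log2 2.68), Ccl7 at 2.99, and the feedback inhibitor Tnfaip3 at 2.09. Il6 was lower at -2.50 (-3.84 to -1.32), on 28 and 8 counts. Immediate early genes had 11 of 16 higher and 2 lower, with a median of 1.25. Klf6 was at 1.94, Jund at -0.34 and the phosphatase Dusp1 at -1.31. Cell cycle genes had 16 of 22 higher and 0 lower, with a median of 0.78. The proliferation marker Mki67 was at 2.02, the cyclin Ccnd1 at 1.58, Mcm6 at 0.40 and Pcna at -0.29. Targets of p53 had 12 of 17 higher and 1 lower, with a median of 0.81. Pmaip1 was at 1.62, Ccng1 at 0.66 and Trp53inp1, the lowest, at -0.92. Of 10000 random lists, 0 were higher than the NF-kappaB, immediate early and cell cycle medians and 1 was higher than that of the p53 targets.

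Cytoskeletal, dedifferentiation and fibrosis genes had 16 of 26 higher and 2 lower, with a median of 0.68, and 0 of 10000 random lists were higher. Ctgf, a matricellular protein, was at 1621 CPM against 32.9 CPM (log2 5.62, interval 5.47 to 5.77). Actb was at 1.26, Krt18 at 0.32 and the fetal protein Afp, the lowest, at -1.64. Of 13 genes that studies of other cell types link to JMJD3, only 5 were measured, with 3 higher and 1 lower. Their median was 1.65, and 4 random lists were higher. The higher members were Inhba at 2.67, Nes at 1.65 and Cdkn2b, named after its values were seen, at 1.99, with Il6 as the lower member.

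Several stress and lipid lists had medians inside the random range. Fatty acid and triglyceride synthesis had 4 of 19 lower and 1 higher, with a median of -0.05, Fasn at 0.76, Acly at -0.17, Me1 at 0.03 and Pnpla3 at -1.82. Cholesterol synthesis had 3 of 23 lower and 0 higher, with a median of -0.22 and 347 random lists lower, Ebp at -1.16 and Sc5d at -0.44. The cholesterol list lay below the random range under 3 alternatives, at percentiles of 1.72 with the length trend removed, 2.21 with random lists matched on length and 2.02 with the GC trend removed, the last chosen after the data were seen. The interferon response had 3 lower and 3 higher among 22 genes, Usp18 at -1.22, Stat2 at -0.81, Bst2 at -0.39 and Ifit2 at 1.07, with a median of -0.15. Endoplasmic reticulum stress genes had 6 lower and 5 higher among 18, with a median of -0.16 and a mean of 0.02, which differ in sign. The chaperones Hsp90b1 and Hspa5 were at -0.75 and -0.37, Sdf2l1 was at -0.86 and Sesn2 at 1.34. Heat shock genes had 2 of 12 lower and 0 higher, with a median of -0.12, Hspa1b at -0.94, Hsp90aa1 at 0.49, Hspa8 at -0.09 and Hsp90ab1 at -0.05. The NRF2 list of oxidative stress genes was outside it, with 9 of 15 lower, 0 higher, a median of -0.71 and 0 random lists lower, Gstm3 at -3.22, Gstm1 at -0.71, Gclc at 0.02 and Abcc4 at 0.38. Circadian clock genes had 6 of 18 higher and 4 lower, with a median of 0.30 and 206 random lists higher. Arntl was lowest at -1.53, Nfil3 was at -1.31, Bhlhe40 at -0.64 and Gm129 highest at 2.76. The clock list lay inside the random range under 5 alternatives.

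**Figure D3:**
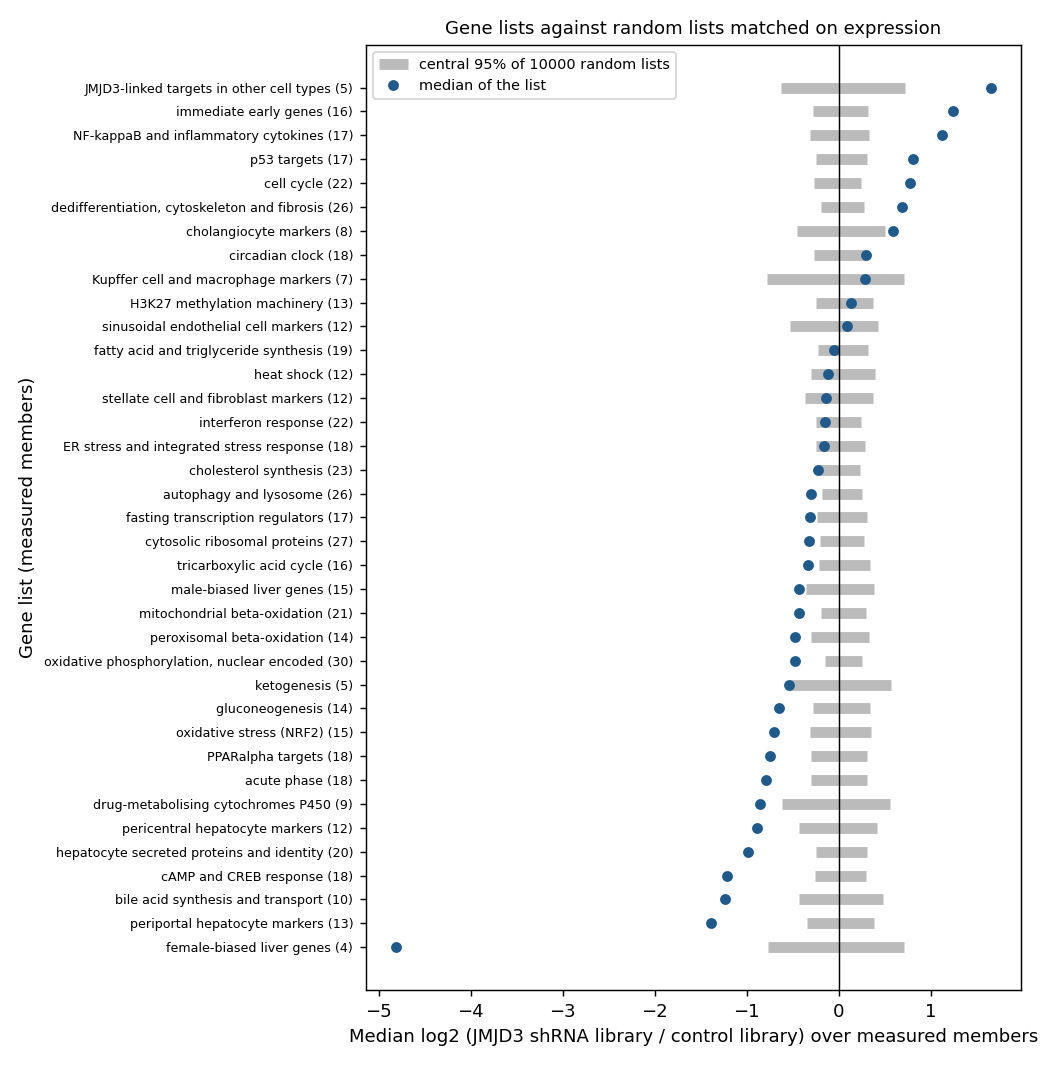
Median log2 ratio of knockdown over control on the horizontal axis for each of the 37 lists on the vertical axis, with the number of measured members in brackets. Points are list medians from 1 library per group and grey bars are the central 95% of 10000 random lists matched on expression; 19 lists lie below their bar, 8 above and 10 inside.

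Across all 12607 measured genes, 1924 (15.3%) passed the rule as higher, 1612 (12.8%) as lower and 9071 as neither. A difference of at least 4-fold was seen in 173 higher and 241 lower genes. Among the 12 highest were Ctgf, Ivl, Lmcd1, Ccl20, Etv5, Fjx1, Efnb2, F3, Emp1, Hmga2 and Cyr61. Cyr61, like Ctgf a secreted matricellular protein, was at 606 CPM against 63.5 CPM, and Ivl, involucrin, had 3 counts in control and a log2 ratio of 6.17 (4.61 to 8.46). Among the 12 lowest were Ntrk2, Cyp17a1, Slco1a4, Agxt2l1, Mmd2, Cps1, Wnt4, Ppp1r3c, Nppc and Hal. Ntrk2, a neurotrophin receptor, was at 0.387 CPM against 63.7 CPM (log2 -7.36, interval -8.68 to -6.31). Mmd2 had 186 counts in control and 1 in knockdown, a log2 ratio of -8.23 (-13.54 to -5.73), and Ppp1r3c, a glycogen-targeting phosphatase subunit, was at -5.37. The authors' deposited table calls 1880 genes higher and 1512 lower at an adjusted p-value under 0.05. In simulated libraries with a biological coefficient of variation of 0.2, 2042 of 12375 unchanged genes passed the rule of size, so the counts of genes depend on a spread that these 2 libraries cannot measure.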

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

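The rerun of edgeR's exact test, the GC trend, the omission of overlapping genes and the halved counts were chosen after the data were seen. All other alternatives were planned. Kdm6b kept a ratio below 1 under each alternative run, from 0.298 with the length trend removed to 0.373 with the GC trend removed. With counts halved its interval widened to 0.315 to 0.421. The beta-oxidation median stayed negative and outside the random range in all 14 alternatives, at -0.48 after removal of the expression trend, -0.49 with upper-quartile scaling, -0.33 after removal of the length trend and -0.59 as a mean, with percentiles up to 0.17. At a 2-fold threshold 926 genes were higher and 781 lower, which follows from the stricter size. Upper-quartile scaling gave 1734 higher and 1820 lower, and the median of all genes stayed between -0.05 and 0.01 under the scalings run. Against 3392 calls in the authors' deposited table, the rerun of edgeR's exact test called 968 at an assumed coefficient of variation of 0.2 and 94 at 0.4, where Kdm6b was not called. Of 27 lists outside the random range, 20 were outside in every alternative and 7 came inside in some. Of the 10 lists inside, ketogenesis and cholesterol synthesis lay outside in some. The cause was not tested for the other shifts. No paired analysis was possible because each group has 1 library, and for the same reason none could be left out. Depth limits genes near the floor of 0.267 and 0.166 CPM, where Cyp7a1 and Cyp8b1 lie in the knockdown library.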

Other observations

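The gene lists of the next paragraph, the levels of single genes after it, and all tests here were chosen after the result was seen, except that of exon length against genomic span and the planned removal of the length trend, and 41 lists were set against random lists in all. For the length test the trend over length classes had been seen, but the partial correlations had not.

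Enzymes of amino acid breakdown and the urea cycle were lower in the knockdown library, 31 of 46 measured genes passing the rule of size and 0 passing as higher, with a median log2 ratio of -1.10. Tdo2, which opens the tryptophan ring, was at 14.2 CPM against 236 CPM (log2 -4.05), Got1 at -3.38 and the abundant glutamate dehydrogenase Glud1 at -1.02. Targets of ERK signalling were higher, 9 of 10 with a median of 2.03, the phosphatase Dusp6 at 2.81 and Spry4 at 2.33. Targets of YAP and TEAD were higher in 17 of 21 with 0 lower and a median of 1.15, among them Ankrd1 at 2.61 and Axl at 1.89. These 3 lists were written with some of their members already seen among the highest or lowest genes, such as Cps1 and Hal, Etv5, and Ctgf and Cyr61, so their place among random lists is no independent evidence and is not given. Mitochondrial ribosome genes had 4 of 30 lower, a median of -0.23 and a percentile of 1.04, which became 17.57 with the length trend removed and 35.94 with random lists matched on length.

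Some liver transcripts were near 0 in both libraries while others were abundant. Alb, at 1519 CPM in control and 794 CPM in knockdown, ranked 32 and 104 among all genes. Fabp1 had 2 counts in each library, Cyp2e1 had 0 in each, Otc had 1 and 3, and Apoa1 was at 3.29 and 2.93 CPM. A count of 0 allows up to 0.267 CPM in control and 0.166 CPM in knockdown. The ribosomal gene Rpl30, in use in all cells, had 1 count in each library, so a near-0 count here can also come from the gene models or from reads left uncounted. The labels name primary hepatocytes, in which Fabp1, Cyp2e1 and Apoa1 are usually abundant, so it stays open whether these levels come from the cells, their state in culture or the counting, and no explanation was tested. The hepatocyte lists carry that doubt. Clu and Spp1 ranked 1 and 2 in both, Spp1 at 7795 and 8011 CPM. The Y-linked Ddx3y was at 122 and 145 CPM and Xist had 1 and 2 counts. Hmgcs1 had 0 counts in both libraries, and its gene model in the files lies on an unplaced part of chromosome 13.

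Longer genes had higher log2 ratios, from a median of -0.35 in the shortest of 10 length classes to 0.36 in the longest, and this held at low, middle and high expression. Holding genomic span constant, the rank correlation of the ratio with exon length across genes was 0.240, against 0.055 for span with exon length held, so the trend goes with transcript length. Genes are not replicates here, and a difference in RNA fragmentation or size selection between the libraries may contribute, as may the knockdown itself. The trend alone leaves the beta-oxidation list apart from random lists, since its percentile among them was 0.02 after removal. Of 37 lists, 19 lay below their random range and 8 above. Hepatocyte secreted proteins and identity genes, with a median of -0.98, and the cyclic AMP list, with -1.22, were lower than the beta-oxidation list. A fall shared with such lists was not tested for beta-oxidation and stays open. A shift shared with 74 other nuclear genes of mitochondria stays open, because the list lay at a percentile of 11.81 among equal-sized lists of those genes as measured (medians of -0.44 and -0.38) and at 0.11 with the length trend removed (-0.33 and -0.14), as does an effect of the shRNA.

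The cyclic AMP list was lower in the knockdown library, 12 of 18 genes passing as lower, where the central 95% of random lists reached up to 5 and the largest had 8. In the same list 4 genes passed as higher, Fosb at 2.38, Fos at 2.30, Junb at 1.76 and Per1 at 0.68. Fosb, Fos and Junb also belong to the immediate early list, in which 11 of 16 genes were higher. The genes that rose therefore do not decide whether the response to forskolin was weaker. A weaker response to forskolin in the knockdown library could produce the lower genes and stays open, because 0 libraries without forskolin were used here. The title calls JMJD3 itself induced by fasting, so a lower Kdm6b does not separate the shRNA from a weaker response. A difference between the pools of cells other than the shRNA cannot be told apart from it either, because there was 1 pool per group.

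Hepatocyte lists were lower, and a smaller share of hepatocytes in the knockdown culture could lower them. If macrophages, stellate cells and endothelial cells had taken up that share, their markers would be higher. Over 31 markers of macrophages, stellate cells and endothelial cells the median log2 ratio was 0.045, with a bootstrap range of -0.23 to 0.20. That range stays under 0.585, which is the 1.5-fold of the rule of size. The limit was not derived from a share of hepatocytes, so the test cannot decide on a smaller rise. The 5 most abundant of them, all from the stellate cell and fibroblast list, went both ways. Col1a1 was at 0.03, Acta2 at 0.41 (0.26 to 0.57), Ecm1 at 0.14, Col1a2 at -0.23 and Col3a1 at -0.29. Of 17 macrophage markers sought, only 7 were measured. Abundant hepatocyte transcripts do not decide the question. Trf and Apob were not lower, but 15 of 20 genes of their list passed as lower, among them Fgb at -2.24 and Ambp at -0.92. Apob, with 13909 bp of exons, also lies in the longest length class, whose median was 0.36. Cholangiocyte markers, which are not among the 31, were higher, with a median of 0.59. Sox9, Spp1 and Krt7 of that list are also known in cultured hepatocytes that lose differentiation. A rise in that cell type or state, and with it a smaller share of hepatocytes, therefore stays open. A biological effect of the knockdown on differentiation stays untested.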
